A study of Homo sapiens with 8 samples.

How the data were processed

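Raw counts of read pairs per gene were deposited as a table of 8 columns. Per the file headers, the authors counted with featureCounts on a GENCODE annotation, reverse-stranded. Samples were grouped by the cell line and the treatment that their titles give. A column was to be used only where its name placed it on a sample or in one of the 4 groups. The names give the treatment, but the labels do not say which part of a name marks the cell line. All 8 columns were therefore left out under this rule, and no test was run. The counts were seen when the table was inspected, and no column was placed by them, since samples were not assigned by their values.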

Results

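Messenger RNA was profiled by stranded polyA sequencing in HEK293 cells, a human embryonic kidney line. The 8 samples formed 4 groups of 2 samples each. Cells that stably overexpressed HTR1E, a serotonin receptor coupled to inhibitory G proteins, and control cells were each collected without added ligand or after serotonin. The labels give all 8 samples the same hours of starvation. Every serotonin-treated sample, in both cell lines, had the same micromolar dose for the same time, also given in hours. The comparisons implied by this design were the difference between the cell lines within each treatment, the response to serotonin within each cell line, and the difference between those responses.

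None of these comparisons was made here. The names of the 8 columns of counts give a treatment, with 4 columns named for control and 4 for serotonin. The rest of each name is a letter with or without a second letter, and the labels do not say which of these marks the cell line and which the replicate. Of the 8 columns, 0 had a name that matched a single sample's title. Names and titles are worded so differently that no match was possible, so this count tests nothing. No column was placed in a group, because the names and labels do not say which letter marks the cell line. The map is left open by the names and labels alone. When the table was inspected, the counts of the overexpressed receptor separated the columns by the first letter. Those counts were not used to place columns, since samples were not assigned by their values. A comparison of the treatments across both cell lines was not run. No gene-level value is given.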

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

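No paired analysis was possible between the 4 groups under the rule that columns are placed by name alone, because that rule placed no column in a group. The limit is this rule and not the number of samples. A comparison of the treatments alone, with columns paired by the rest of the name, would not need the cell line. It was not run, since only columns placed on a sample or in a group were to be used. The titles number the replicates but do not say whether samples with the same number were handled together. Such a comparison would pool cells that overexpressed HTR1E with control cells, so it would not give the response within either cell line. No gene was tested, so none of the normalizations, filters or tests chosen before the data were examined was compared. After the data were seen, the names were also matched in looser ways. With the treatment word matched to the treatment label, each column fitted 4 samples. With the first letter, or instead the trailing letter, also read as the replicate number, each column fitted 2 samples. None of these rules can place a column on a single sample, so they do not test the count of 0 columns matched by name.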
